A study of Homo sapiens with 6 samples.

How the data were processed

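RNA was measured by sequencing in 786-O cells carrying control guide RNA (3 libraries) or PHF8 guide RNA (3 libraries). Per the labels, total RNA was extracted with Trizol, RNA of high integrity was used and libraries followed standard Illumina protocols. Per the labels' series design text, reads were filtered, mapped to the human genome (GRCh38, NCBI) with HISAT2 and counted per gene with HTSeq. The submitters' processing notes give HISAT2 version 2.0.4. The HTSeq version, the strand setting and the annotation release are not given in the sources used here. The series design text also states DESeq2 with a fold change above 2 or below 0.5 and an adjusted p under 0.05; the authors' own gene calls were not used here.

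The deposited values are raw read counts per gene symbol, whole numbers with no normalization, for 54261 symbols in 6 libraries. Each column was tied to its sample by its name, which is the sample's title. Totals ran from 21533615 (control library 1) to 29095133 (knockout library 3). Genes that share reads with near-identical copies, or that overlap a gene on the other strand, are uncertain because it is not known how such reads were counted. Coordinates and gene classes come from GENCODE annotation on GRCh38, matched by symbol: 46202 symbols matched directly, 1604 by an older symbol or synonym and 6455 not at all.

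The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) of knockout against control, with group as the only term. Library sizes were scaled by TMM factors (1.05 to 1.07 in control, 0.94 to 0.96 in knockout libraries), and genes were kept by edgeR's filterByExpr, which left 14398. Fold changes used a prior count of 0.125, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes. CPM values are scaled by the same factors unless library totals are named, and SE is the log2 fold change divided by the root of the test's F. For a gene with 0 reads in a group, the fold was computed against a floor of 3 counts over the group. The biological coefficient of variation was 14.1% over both groups, 10.3% among control and 17.3% among knockout libraries. The first principal component held 80.9% of the variance and separated the groups. No libraries were duplicates: counts of libraries of the same group differed by more than sampling noise, with chi-square per degree of freedom from 3.10 to 75.7. FN1, which encodes fibronectin, took 0.89% to 0.93% of counts in control libraries and 3.04%, 1.35% and 2.26% in knockout libraries 1, 2 and 3.

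The following were fixed before the data were examined: the test, the 37 gene lists, the alternative settings listed here and the rule for naming genes. The text names PHF8; in each direction the 10 largest fold changes among protein-coding genes with an adjusted p under 0.05, a mean of at least 5 CPM and groups that do not overlap; 14 genes chosen in advance for this cell type; and up to 4 members with the smallest p among the called genes of each list. XIST and Y-linked genes were left out of naming. Lists with 5 or more tested members, 33 in all, were tested with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, again with an estimated correlation, and with fry. Of these 33 lists 10 passed with the preset correlation and 0 with an estimated one. The lists covered chromatin, hypoxia, lipid and glutamine metabolism, stress, cell cycle, immunity, adhesion, kidney identity, ribosomes, mitochondria and markers of other cell types; 971 of their 977 symbols were found. The results of 1 list that did not pass and of 3 further genes are not reported here. The counts of members that rose or fell are adjusted over all tested genes. Adjusted over the list alone they were the same except for cholesterol synthesis (22 rose), matrix (9 rose), TGF-beta and YAP targets (4 rose), proximal tubule (6 fell), ribosome biogenesis (7 fell), cancer-testis antigens (6 fell) and endothelial markers (1 rose).

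Alternatives were DESeq2 1.42.0, limma-voom, median-ratio and upper-quartile factors, library totals only, no filter, a stricter filter (over 1 CPM in all 3 libraries of a group), robust dispersions, the replicate number as a block, leaving out each library, and a test against 2-fold itself. An offset for transcript length and GC content was added after seeing the data: per library, smooth trends (lowess span 0.3) were removed for the 91.6% of tested genes with both values. These trends were fitted around the mean of all libraries, so a group difference that follows length or GC content is removed with them.

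The analysis was tested on simulated counts for these 14398 genes with the spread of this comparison and 200 genes changed. It recovered 31.3% of 67 genes changed 1.5-fold, 89.6% of 67 changed 2-fold and 100% of 66 changed 4-fold, and 12 of its 159 calls were unchanged genes. In a second simulation, made after seeing the data, the other 8468 called genes were also changed, to the levels of their groups. It recovered 91.0% of the same 67 genes at 1.5-fold and all at 2-fold and 4-fold, and 172 of its 7847 calls were unchanged genes. In a separate draw with only the genes of a planted list changed, that list was called and 0 of 35 random lists were. Genes were drawn independently of each other there, so this does not test the preset correlation. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.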

Results

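Gene expression was measured by RNA-seq in 786-O cells, an established human clear cell renal carcinoma line that lacks functional VHL, the protein that marks hypoxia-inducible factors for degradation. The cells carried either control guide RNA or guide RNA against PHF8, delivered with CRISPR-Cas9, and the PHF8-guide cells are described as PHF8 knockout. PHF8 is a histone demethylase of the JmjC family that removes repressive methyl marks. There were 3 control and 3 knockout libraries, with 21533615 to 29095133 counted reads each. The labels do not say whether the knockout cells were a pool or a clone. They also do not say whether the 3 libraries of a group came from separate cultures or carried the same guide RNA. The p-values therefore measure the spread between these libraries, which may be technical. The comparison asks which transcripts differ between knockout and control cells.

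The PHF8 transcript (chromosome X, 53936676 to 54048958, GRCh38) fell in all 3 knockout libraries. Its level was 34.8 ± 1.83 CPM (read count scaled by library size; SD, n = 3) in control cells and 10.1 ± 3.08 CPM (SD, n = 3) in knockout cells. The log2 fold change was -1.78 (SE 0.21; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.19e-04). Knockout libraries 1, 2 and 3 retained 31.0%, 19.3% and 36.7% of the control mean. Counts summed over the gene do not show whether the remaining transcripts carry an edit.

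GLUL, which encodes glutamine synthetase (chromosome 1, 182378098 to 182392206, GRCh38), had 374, 351 and 362 reads in the control libraries and 0 reads in each knockout library. Control cells held 15.5 ± 1.60 CPM (SD, n = 3, by library totals). With a floor of 3 counts over the 80648498 reads of the knockout group, GLUL was at least 417-fold lower in knockout cells. Intervals and floors cover counting error only. Among the 10688 genes with a mean of at least 100 reads in control cells, GLUL was the only one with 0 reads in all 3 knockout libraries. Of the 8213 other genes at least as abundant as GLUL in control cells, the lowest share of the control level in knockout cells was that of PLAC8, 5.08%. That share is a mean, and PLAC8 kept 1.72%, 0.93% and 12.6% in knockout libraries 1, 2 and 3. The gap to GLUL rests largely on library 3, because shares among genes this abundant went down to 0.0% in libraries 1 and 2 (given below).

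**Figure D1:**
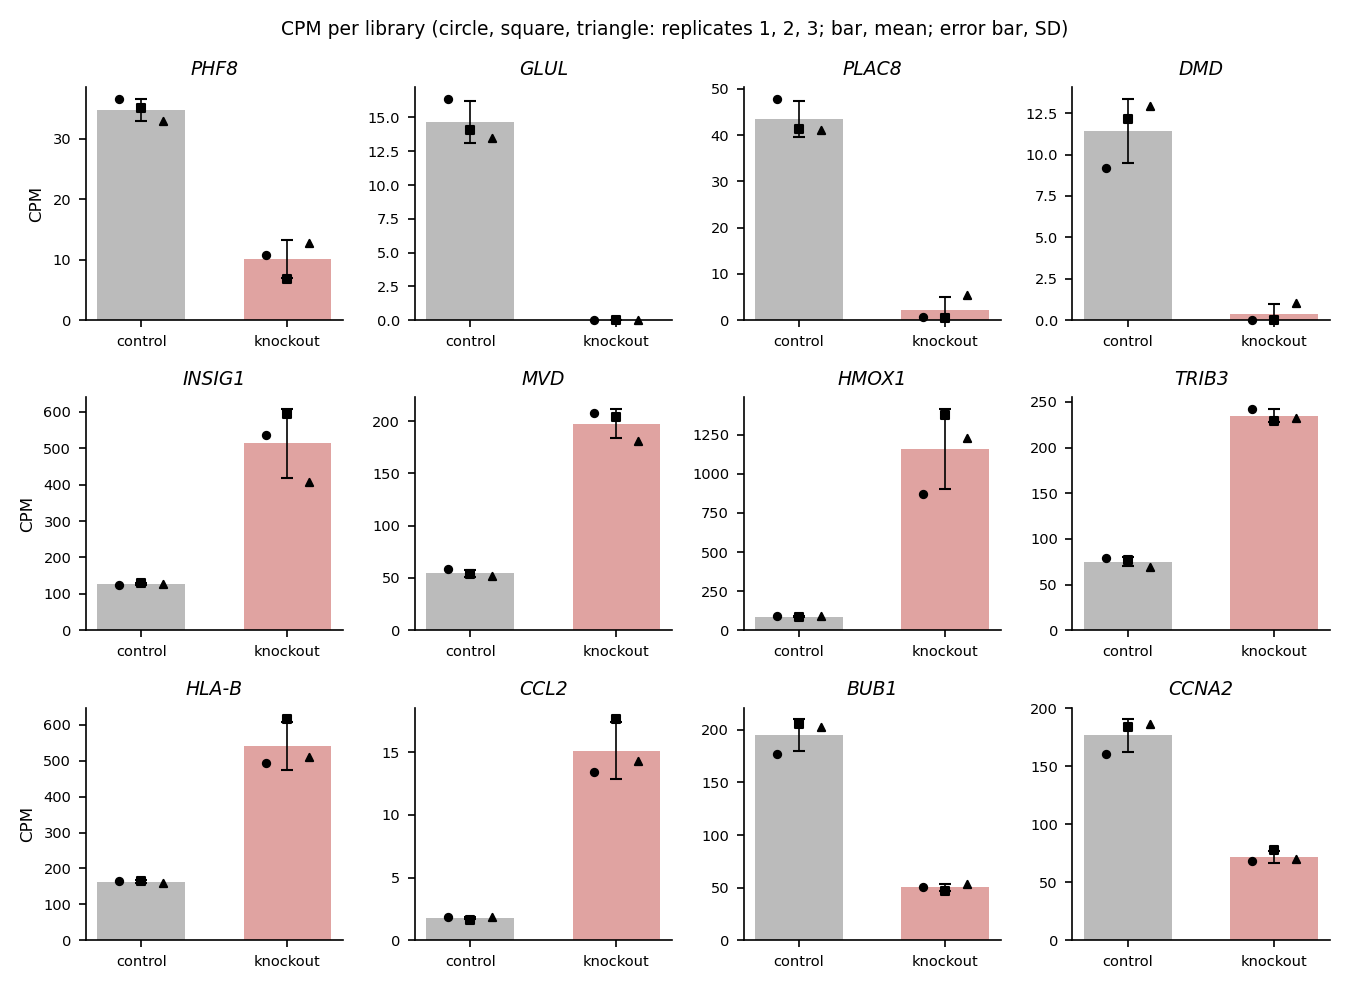
CPM (vertical axes, linear, starting at 0) of 12 genes in control and knockout libraries; bars are means, error bars SD and symbols the 3 libraries of each group. PHF8 lay at 10.1 CPM in knockout against 34.8 CPM in control cells, GLUL at 0 in all 3 knockout libraries, and the other genes are named in the text.

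The difference between the groups was broad. Of 14398 tested genes, 8593 (59.7%) passed an adjusted p of 0.05, 4158 higher and 4435 lower in knockout cells. With the 2-fold criterion of the series added, 1324 genes rose and 2038 fell, 3362 in all. The 3 knockout libraries lay entirely to one side of the 3 control libraries in 9615 genes (66.8%), against 10% by chance. Without scaling factors beyond library totals, the median of all tested genes shifted to -0.18 log2, from -0.01, and 36.7% of the called genes were higher instead of 48.4% (26.6% instead of 39.4% past 2-fold).

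Fold changes ran with transcript length and GC content across genes. In 4 bins of transcript length with like numbers of genes, the shortest bin had a median log2 fold change of 0.33 and the longest -0.59, and in 4 such bins of GC content the lowest had -0.64 and the highest 0.43. Across genes, which are not independent replicates, Spearman's rank correlation was -0.41 with length and 0.49 with GC content, and libraries of the same group also differed along both measures. After an offset for both, an alternative chosen after seeing the data, 8429 genes passed, 2334 of them only with the offset. Of the 8593, 5659 passed in the same direction with the offset, 436 passed in the opposite direction and 2498 no longer passed. Of the 3362 genes past 2-fold without the offset, 2870 passed by adjusted p alone in the same direction with it, whether or not they stayed past 2-fold. With the offset 2303 genes in all were past 2-fold, 1152 of them higher. Of 135 named members of the gene lists past the threshold, 34 kept less than 50% of their log2 fold change with the offset and 31 had a larger one. Besides genes whose values with the offset are given below, the 34 include JMJD6, TRIM28, ACADVL, ECI1, RRM2B, PHLDA3, FEN1, CDT1, POLA1, CLSPN, HLA-C, KRT7, PKP3, IER2, RPL13, NDUFS7 and COX4I1. Fold changes and counts of genes are without the offset unless it is named.

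Among protein-coding genes with a mean of at least 5 CPM, HSPA6, a heat-inducible chaperone gene, had the largest fold rise in the main analysis, from 0.51 ± 0.10 to 28.4 ± 6.41 CPM (SD, n = 3 each, log2 fold change 5.79, SE 0.26; edgeR adjusted p = 2.12e-06). RARRES2, which encodes the adipokine chemerin, rose from 11.1 ± 1.35 to 469 ± 70.8 CPM (SD, n = 3 each, log2 fold change 5.40, SE 0.16). PTGDS, a prostaglandin D synthase, rose 26.2-fold and QPRT, an enzyme of NAD synthesis from tryptophan, 20.6-fold. AKR1C1, an aldo-keto reductase, rose 27.6-fold and the serine protease gene PRSS12 rose 30.3-fold. ANXA8L1, PLBD1, the transcription factor gene IRF8 and the organic anion transporter gene SLCO2B1 rose between 15.2-fold and 20-fold. AKR1C1, HSPA6 and ANXA8L1 have close paralogs, so the split of their reads between copies is uncertain.

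Among the same class of genes the largest fall after GLUL in the main analysis was that of RAB31, a small GTPase of vesicle traffic, from 11.1 ± 1.25 to 0.27 ± 0.12 CPM (SD, n = 3 each, log2 fold change -5.31, SE 0.26; edgeR adjusted p = 3.19e-06). MXRA5, a matrix protein gene, had a log2 fold change of -4.18 (SE 0.26) and the ubiquitin ligase gene HERC3 one of -3.83 (SE 0.21). DMD, PLAC8, AGTRAP, CENPV, the receptor-like kinase gene PTK7 and the actin regulator gene WASF3 completed the 10, with log2 fold changes from -4.91 (DMD) to -3.64 (WASF3). The size of these 6 falls, and so their order, depended on knockout library 3. Without it the log2 fold changes were -6.23 for PLAC8, -5.47 for PTK7 and -4.92 for AGTRAP, against -4.26, -3.96 and -4.13 with it, and DMD, CENPV (-7.20), WASF3 (-6.55) and PLAC8 fell further than RAB31 (-5.72). DMD and CENPV also fell further than RAB31 with limma-voom. Among the rises, AKR1C1 (5.60) lay above HSPA6 (5.32) with the length and GC offset. CENPV kept 0.85%, 0.41% and 16.9% of its control level in knockout libraries 1, 2 and 3, and WASF3 kept 0.82%, 1.20% and 21.1%. DMD had 0, 0 and 29 reads there, which makes it at least 208-fold lower in knockout libraries 1 and 2 with a floor of 3 counts over their 51553365 reads.

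**Figure D2:**
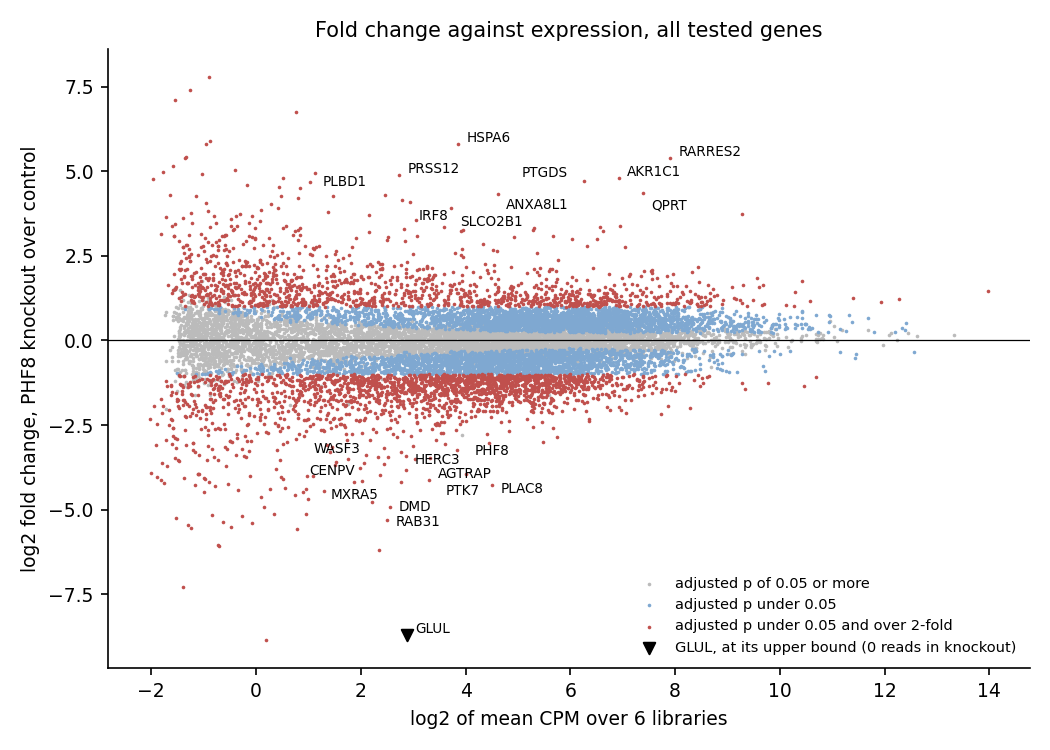
Log2 fold change of knockout over control (vertical axis) against log2 mean CPM (horizontal axis) for the tested genes; colours mark adjusted p and 2-fold, and labels the targeted gene and the largest rises and falls. RARRES2 lies at 5.40 and PHF8 at -1.78; GLUL is drawn at its bound, -8.71, and other genes with a group at 0 at their fitted values.

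Genes of cholesterol synthesis and uptake rose together. Of 25 tested, 20 rose, 0 fell and 5 did not pass the test, with a median log2 fold change of 1.10 (camera adjusted p = 1.94e-06, over 33 lists; adjusted p = 0.44 with an estimated correlation). INSIG1, a sterol-regulated retention protein of the endoplasmic reticulum, rose from 127 ± 2.20 to 514 ± 95.8 CPM (SD, n = 3 each, log2 fold change 2.02, SE 0.14). The synthesis enzyme genes MVD, NSDHL and FDFT1 rose 3.62-fold, 3.03-fold and 2.69-fold.

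Other lipid lists moved less uniformly. In fatty acid and triglyceride synthesis 10 of 25 genes rose and 5 fell (median 0.22; camera adjusted p = 0.25); with the length and GC offset 18 rose and 2 fell and the list passed (median 0.42, adjusted p = 0.0045, with 0.0045 to 0.45 over all alternatives with the preset correlation). The list also passed as higher with fry (adjusted p = 0.029). FASN, the fatty acid synthase, rose from 193 ± 5.93 to 441 ± 149 CPM (edgeR adjusted p = 1.31e-03) and the desaturase gene SCD from 398 ± 13.6 to 851 ± 141 CPM (adjusted p = 1.01e-04; SD, n = 3). SREBF1, a transcription factor of lipid synthesis, rose 1.49-fold, and DGAT2 and DGAT1, which complete triglyceride synthesis, rose 2.46-fold and 1.87-fold. AGPAT2 rose 1.65-fold, but lay at 0.0075 on the log2 scale with the offset. In the lipid droplet list 6 of 16 genes rose and 4 fell (adjusted p = 0.75; 6 and 6 with the offset). PLIN2, the main droplet coat gene of this tumour type, rose from 581 ± 28.3 to 909 ± 112 CPM, while the lipase gene LIPE and the caveolin gene CAV1 fell 6.87-fold and 2.16-fold. FABP6 rose 4.48-fold, and SOAT1 fell 1.70-fold but lay at 0.18 on the log2 scale with the offset. CD36, a fatty acid transporter, had 0 or 1 read per library and was not tested. In fatty acid oxidation 7 of 22 genes rose and 7 fell (adjusted p = 0.78; 6 and 9 with the offset), EHHADH and PDK4 falling 4.0-fold and 3.73-fold and ECI1 and ACADVL rising 2.04-fold and 1.83-fold. CPT1A, which admits fatty acids to mitochondria, fell by 0.45 on the log2 scale (adjusted p = 0.033), a call lost without control library 1 (adjusted p = 0.11) or control library 2 (adjusted p = 0.10, with 0.0022 to 0.11 over all alternatives).

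Targets of hypoxia-inducible factors, which VHL marks for degradation where it is functional, rose by a small margin. Of 27 tested, 13 rose and 3 fell (median 0.26; camera adjusted p = 0.044; adjusted p = 0.32 with an estimated correlation). The call was lost with library totals only (adjusted p = 0.059), the length and GC offset (adjusted p = 0.081), the replicate block (adjusted p = 0.057), or without control library 3 (adjusted p = 0.052) or knockout library 2 (adjusted p = 0.075, with 0.020 to 0.081 over all alternatives with the preset correlation). LOX, a collagen crosslinking enzyme, rose 4.52-fold, P4HA2 2.18-fold and the secreted hormone gene STC2 1.87-fold, while KDM3A fell 2.39-fold. CCND1, the cyclin D1 gene, rose 1.23-fold (edgeR adjusted p = 0.015), a call lost without control library 2 (adjusted p = 0.053) or knockout library 3 (adjusted p = 0.062) and with library totals only (adjusted p = 0.21, with 4.24e-04 to 0.21 over all alternatives). EPAS1, which encodes HIF-2α, had a log2 fold change of 0.01 (SE 0.11) and VHL one of -0.15 (SE 0.10), neither past the threshold. VHL passed with library totals only (-0.32, adjusted p = 0.018) and lay at 0.15 with the length and GC offset (adjusted p = 0.11). EPAS1 passed in no alternative, at -0.16 with library totals only and 0.15 with the offset. HIF1A fell by 0.44 on the log2 scale (adjusted p = 0.011), but lay at 0.14 (adjusted p = 0.16) with the length and GC offset and lost the call without control library 2 (adjusted p = 0.061) or 3 (adjusted p = 0.062, with 2.15e-04 to 0.16 over all alternatives). Among 17 glycolysis genes 6 rose and 4 fell (camera adjusted p = 0.64), with ALDOA and PGK1 1.79-fold and 1.39-fold higher, ENO2 1.55-fold lower and PFKM lower by 0.58 on the log2 scale. With the length and GC offset 3 rose and 10 fell (median -0.23, adjusted p = 0.10), and ALDOA lay at 0.20 on the log2 scale.

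In the glutamine and glutamate list 9 of 26 genes rose and 8 fell (median 0.04, also with GLUL at its bound; camera adjusted p = 0.87), and with the offset 12 rose and 8 fell (median 0.26). The list passed as lower with fry (adjusted p = 0.012), though camera put it on the higher side. PYCR1, ASNS and GPT2, enzymes of proline, asparagine and alanine synthesis, rose 4.46-fold, 3.56-fold and 2.22-fold.

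Genes of 2 stress programmes rose. Of 23 genes of the ATF4 integrated stress response, 18 rose and 1 fell (median 0.81; camera adjusted p = 6.92e-05; adjusted p = 0.32 with an estimated correlation). The stress cytokine gene GDF15 rose 9.60-fold, NUPR1 5.98-fold, the pseudokinase gene TRIB3 3.13-fold and the amino acid transporter subunit gene SLC3A2 3.12-fold. Among NRF2 targets and ferroptosis genes 16 of 22 rose and 3 fell (median 0.77; camera adjusted p = 2.85e-04; adjusted p = 0.44 with an estimated correlation). HMOX1, the inducible haem oxygenase, rose from 87.4 ± 2.87 to 1161 ± 258 CPM (SD, n = 3 each, log2 fold change 3.73, SE 0.17; edgeR adjusted p = 2.21e-06), and AKR1B10 and AKR1C3 rose 8.07-fold and 4.18-fold. All 4 tested metallothionein genes rose, MT1X 10.2-fold, MT1F 3.68-fold, MT2A 2.98-fold and MT1E 2.65-fold, too few for a list test and with reads that may be shared within the family. Chaperone and unfolded protein response genes were mixed, with 7 of 18 higher and 5 lower (camera adjusted p = 0.57), XBP1 rising 2.10-fold, HERPUD1 1.70-fold and PDIA6 1.45-fold. SEL1L fell 2.12-fold, a call lost with the offset (log2 fold change -0.061). Of 21 p53 targets 8 rose and 9 fell (camera adjusted p = 0.87), RRM2B among the falls with a log2 fold change of -1.57 and PHLDA3 among the rises with 0.72. MDM2 fell 1.92-fold, but lay at 0.056 on the log2 scale with the offset. Immediate early genes, which respond to handling of cultures, had 9 of 18 higher and 4 lower (camera adjusted p = 0.41), but 4 higher and 7 lower with the offset (median -0.06). Among them EGR1 fell 5.35-fold while EGR2 rose 5.93-fold, IER2 1.95-fold and MYC rose from 102 ± 2.80 to 168 ± 16.5 CPM (SD, n = 3 each).

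Genes of G2 and mitosis fell. Of 36 tested, 29 fell, 1 rose and 6 did not pass the test (median -1.06; camera adjusted p = 1.94e-06; adjusted p = 0.32 with an estimated correlation). The spindle checkpoint kinase gene BUB1 fell from 195 ± 15.6 to 50.2 ± 3.56 CPM (SD, n = 3 each, log2 fold change -1.96, SE 0.11; edgeR adjusted p = 4.79e-06). BUB1B fell 3.03-fold, NUSAP1 3.01-fold and the cyclin gene CCNA2 2.45-fold. S phase and replication genes had 6 of 38 higher and 13 lower and did not pass camera (adjusted p = 0.58), but passed as lower with fry (adjusted p = 0.014). The licensing factor gene CDT1 rose 1.84-fold and the nuclease gene FEN1 1.75-fold, while POLA1 and CLSPN fell 2.40-fold and 2.50-fold. Of 8 replication-dependent histone genes 4 rose and 1 fell (camera adjusted p = 0.15), HIST1H1C rising 4.37-fold, HIST1H2AC 4.11-fold and HIST1H2BK 2.84-fold. HIST1H2BH fell 4.20-fold (edgeR adjusted p = 0.015), a call lost without control library 1, control library 3 or knockout library 3, and its log2 fold change of -2.07 was -3.28 without knockout library 1.

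**Figure D3:**
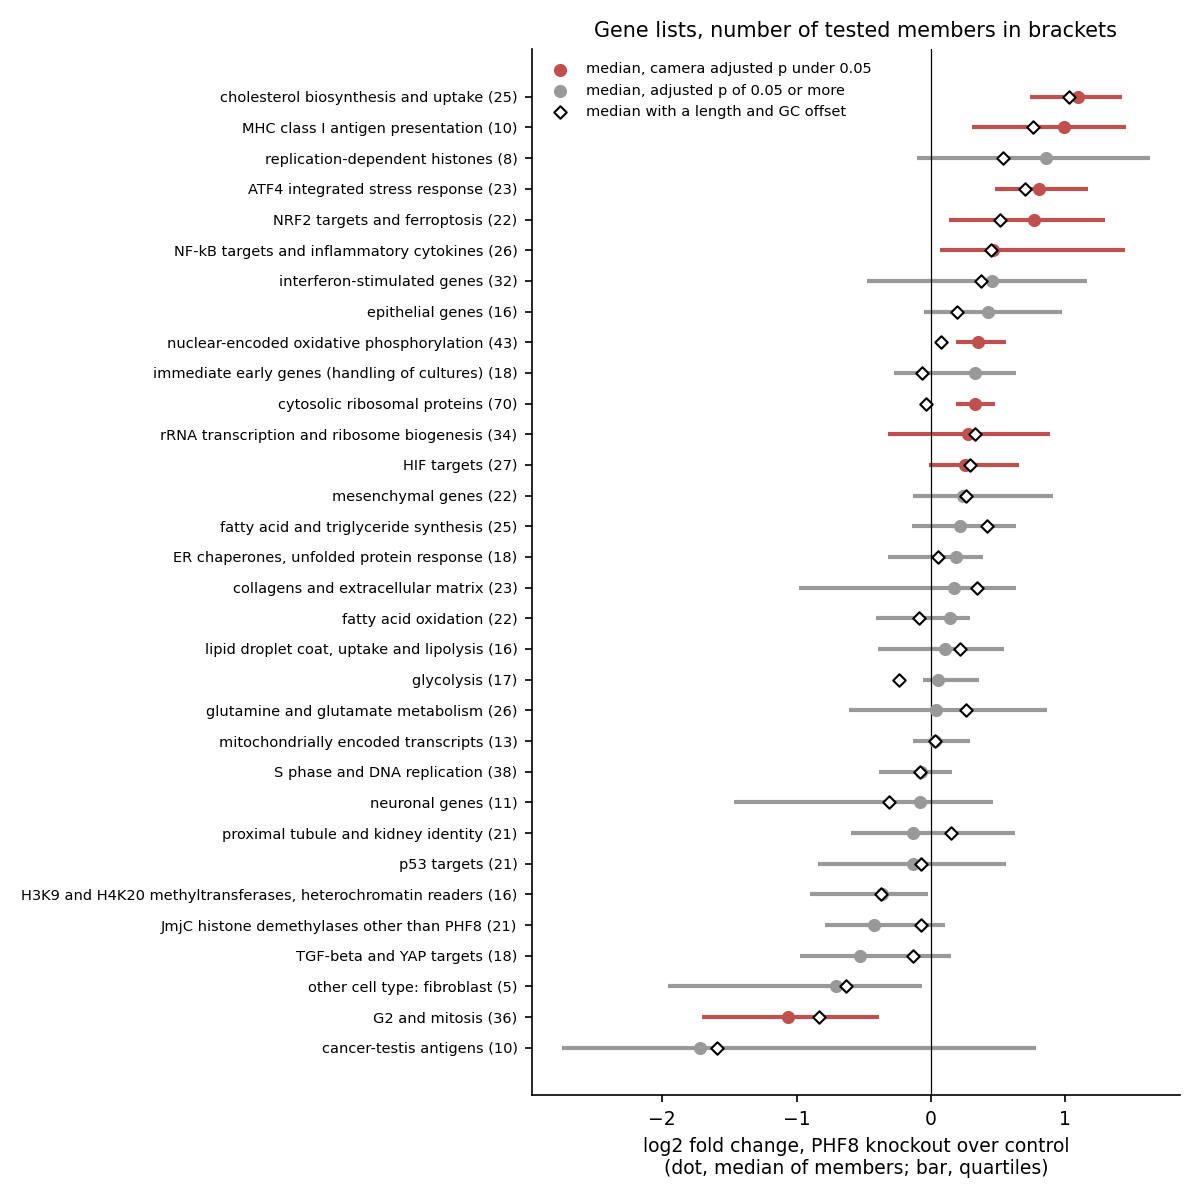
Median log2 fold change (horizontal axis) of the gene lists reported here with 5 or more tested members (vertical axis, member number in brackets); bars span the quartiles, red marks camera adjusted p under 0.05 and open diamonds the medians with a length and GC offset. Cholesterol synthesis has the highest median among the red lists, 1.10, and mitosis the lowest, -1.06, while ribosomal proteins move from 0.33 to -0.04 with the offset.

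Inflammatory and antigen presentation genes rose. Of 26 NF-kB targets and cytokines 16 rose and 5 fell (median 0.46; camera adjusted p = 0.0086; adjusted p = 0.32 with an estimated correlation). The chemokine gene CCL2 rose from 1.77 ± 0.11 to 15.2 ± 2.26 CPM (SD, n = 3 each), SAA1 rose 6.42-fold and RELB 2.80-fold, while the adhesion molecule gene VCAM1 fell 2.49-fold. Of 10 MHC class I presentation genes 7 rose and 1 fell (median 0.99; camera adjusted p = 0.031; adjusted p = 0.32 with an estimated correlation), a call lost without control library 1 (adjusted p = 0.066, with 0.0019 to 0.066 over all alternatives with the preset correlation). HLA-B rose 3.32-fold and HLA-C 2.12-fold, with reads that may be shared between HLA genes, and the immunoproteasome gene PSMB10 rose 2.74-fold. Among interferon-stimulated genes 15 of 32 rose and 9 fell (median 0.46; camera adjusted p = 0.11), and the list passed with the length and GC offset (adjusted p = 0.031, with 0.031 to 0.21 over all alternatives with the preset correlation). It also passed as higher with fry (adjusted p = 0.0026). BST2 rose 4.12-fold, MX1 4.63-fold, OAS1 3.86-fold and IFI6 2.94-fold. Of 14 immune cell markers only CD68, a lysosomal protein gene not limited to macrophages, was expressed enough to be tested, and it rose 2.59-fold.

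Among histone modifiers other than PHF8 more genes fell than rose, without a list passing camera, though both lists passed as lower with fry (adjusted p = 0.029 and 0.0052). Of 21 JmjC demethylases 11 fell and 2 rose (median -0.42; camera adjusted p = 0.082), a list that passed without knockout library 1 (adjusted p = 0.039) and without the expression filter (adjusted p = 0.023, with 0.023 to 0.45 over all alternatives with the preset correlation). With the length and GC offset 8 fell and 4 rose (median -0.076, adjusted p = 0.45), and without knockout library 2 the median was -0.25. KDM5B fell 2.81-fold, KDM3A 2.39-fold and KDM5A 2.16-fold, while JMJD6 rose 1.76-fold. With the offset KDM5B lay at -0.64 on the log2 scale (-1.49 without it), and the KDM5A call was lost (log2 fold change -0.15). Of the close relatives of PHF8, PHF2 had a log2 fold change of -0.18 (SE 0.14), which passed only with library totals alone (-0.35, adjusted p = 0.048), and KDM7A one of -0.79 (edgeR adjusted p = 0.0097), which lay at 0.32 with the length and GC offset (adjusted p = 0.20, with 0.0031 to 0.20 over all alternatives). Of 16 genes for H3K9 and H4K20 methyltransferases and heterochromatin readers 10 fell and 3 rose (median -0.36; camera adjusted p = 0.11; adjusted p = 0.043 without the expression filter and 0.043 to 0.45 over all alternatives with the preset correlation). Among them CBX5, ATF7IP and CBX1 fell 2.62-fold, 2.67-fold and 1.65-fold and TRIM28 rose 1.49-fold. With the offset 7 of the list fell and 4 rose, and CBX5 and ATF7IP moved from -1.39 and -1.41 to -0.36 and -0.38 on the log2 scale.

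Ribosomal protein and respiratory chain genes were higher by small amounts as lists, calls that ended with the length and GC offset. Of 70 ribosomal protein genes 40 rose and 0 fell (median 0.33; camera adjusted p = 1.18e-04; adjusted p = 0.71 with an estimated correlation and 0.066 with fry), and with the offset 16 rose and 17 fell and the median was -0.04 (adjusted p = 0.80, with 4.51e-06 to 0.80 over all alternatives with the preset correlation). Of 43 nuclear genes of oxidative phosphorylation 24 rose and 2 fell (median 0.35; camera adjusted p = 8.01e-04; adjusted p = 0.71 with an estimated correlation), and with the offset 16 rose and 10 fell and the median was 0.07 (adjusted p = 0.52, with 1.93e-04 to 0.52 over all alternatives with the preset correlation). RPL9 rose 1.93-fold, RPL13 1.69-fold, RPL28 1.60-fold, NDUFS7 2.05-fold and COX4I1 1.71-fold. RPS2 and UQCRC1 rose 1.69-fold and 1.62-fold, calls lost with the offset, while RPL9 kept a log2 fold change of 0.86 (0.95 without it) and RPL28 one of 0.66 (0.68 without it). Ribosome biogenesis genes also rose, 19 of 34 with 5 lower (median 0.28; camera adjusted p = 0.049; adjusted p = 0.71 with an estimated correlation). UBTF, a factor of rRNA transcription, rose 2.49-fold, POLR1C 2.69-fold, NOP56 2.24-fold and NOB1 2.24-fold. That list lost its call without control library 1 (adjusted p = 0.083), control library 3 (adjusted p = 0.061), knockout library 2 (adjusted p = 0.075) or knockout library 3 (adjusted p = 0.053), and with median-ratio factors (adjusted p = 0.051), upper-quartile factors (adjusted p = 0.052) or the replicate block (adjusted p = 0.087, with 0.022 to 0.087 over all alternatives with the preset correlation). Of 13 mitochondrially encoded transcripts 4 rose and 1 fell (camera adjusted p = 0.67), ND6 falling 2.36-fold (edgeR adjusted p = 6.45e-04) and ND3, COX3 and ND1 rising 1.49-fold, 1.43-fold and 1.39-fold.

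Adhesion, matrix and differentiation lists did not pass camera. With fry the epithelial and mesenchymal lists passed as higher and the TGF-beta and YAP targets as lower (adjusted p = 0.0023, 0.014 and 0.0041). Epithelial genes had 7 of 16 higher and 2 lower (median 0.42; camera adjusted p = 0.11), CLDN4, a tight junction claudin, rising 8.50-fold, KRT7 2.35-fold and PKP3 1.86-fold and EPCAM falling 2.74-fold. With the offset 6 were higher and 5 lower (median 0.20). Mesenchymal genes had 10 of 22 higher and 4 lower (camera adjusted p = 0.16), SPARC rising 2.10-fold, LOXL2 2.37-fold, MMP9 3.71-fold and TGFBI 1.62-fold. Collagens and other matrix genes had 8 of 23 higher and 7 lower (camera adjusted p = 0.72), with LAMB3, COL7A1 and COL6A2 rising 3.86-fold, 3.09-fold and 2.29-fold. With the offset 14 were higher and 4 lower (median 0.35, adjusted p = 0.081). Of 18 TGF-beta and YAP targets 10 fell and 3 rose (camera adjusted p = 0.19), CTGF, INHBA and CYR61 falling 2.89-fold, 2.19-fold and 1.75-fold while PMEPA1 rose 2.45-fold. With the offset 7 fell and 4 rose (median -0.13), and INHBA moved from -1.13 to -0.25 on the log2 scale. Proximal tubule genes had 8 of 21 higher and 5 lower (camera adjusted p = 0.78), with GGT1 and ASS1 2.82-fold and 2.64-fold higher and MME 5.22-fold lower. With the offset 6 were higher and 6 lower.

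Among genes foreign to kidney epithelium, cancer-testis antigens had 2 of 10 higher and 5 lower (median -1.72; camera adjusted p = 0.60), with MAGED2 and MAGED1, which are expressed in many normal tissues, rising 2.77-fold and 2.65-fold and MAGEC2 and MAGEA12 falling 6.40-fold and 20.9-fold. MAGEA12 had 0, 0 and 4 reads in knockout libraries 1, 2 and 3, and its log2 fold change of -4.17 was -7.67 without knockout library 3. Neuronal genes had 3 of 11 higher and 5 lower (camera adjusted p = 0.51), MAP2, a dendritic microtubule protein, falling from 3.39 ± 0.49 to 0.07 ± 0.02 CPM (SD, n = 3 each), SYT1 11.3-fold and NCAM1 2.25-fold. The neuronal list passed as lower with fry (adjusted p = 2.98e-04). The log2 fold change of SYT1, -3.39, was -4.94 without knockout library 3. TUBB3 rose 1.74-fold, a call lost with the offset. Fibroblast markers had 1 of 5 higher and 2 lower (camera adjusted p = 0.51), PDPN rising 1.54-fold and LUM and PDGFRB falling 6.20-fold and 3.92-fold, and 2 of 4 endothelial markers rose, TEK and KDR, both at or below 1.49 CPM. The KDR call (adjusted p = 0.048) was lost in every fit without 1 library except that without knockout library 1, with adjusted p from 0.057 to 0.17, and with DESeq2, limma-voom and library totals only. No clustered protocadherin passed the expression filter.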

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

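The fit with the length and GC offset was chosen after seeing the data; the other alternatives were chosen before the data were examined. Counts of called genes stayed within 1.5 times the 8593 and 3362 of the main analysis in every alternative except a test against 2-fold itself, which by its stricter question called 1354 genes. DESeq2 called 8381 genes, 3498 past 2-fold, and 8036 of the 8381 were among the 8593. Leaving out 1 library gave 7170 to 9542 genes, 3195 to 3713 past 2-fold and 8 to 11 lists. Of the 33 lists, 10 passed; with an estimated correlation 0 passed, and with fry, which asks whether a list's genes move on balance one way and compares them with no other genes, 23 did. Ribosomal proteins did not pass fry (adjusted p = 0.066). Among lists outside the camera calls, fry also called the unfolded protein response, immediate early and replication-dependent histone lists as higher (adjusted p = 0.033, 0.014 and 0.0027). It called fibroblast markers as lower (adjusted p = 0.049). PHF8 stayed past the threshold in all alternatives, from -1.99 to -1.56 on leaving out 1 library.

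Of 163 named gene results, 145 kept their direction and side of the threshold in all alternatives. So did 15 of the 33 lists in the alternative fits, a count that leaves out the estimated correlation and fry. Of the results past the threshold in the main analysis, those that reversed all did so with the length and GC offset: ribosomal proteins had a median of -0.038, and KDM7A lay at 0.32, HIF1A at 0.14, SOAT1 at 0.18 and MDM2 at 0.056, none past the threshold; beyond the removal of these trends the cause was not tested. Values not past the threshold also changed sign under several alternatives, among them EPAS1 (-0.16 with library totals only, 0.15 with the offset), VHL and 9 lists. None of these passed with the sign turned in the alternative fits. With fry, though, the glutamine and glutamate list passed as lower (adjusted p = 0.012), while camera put it on the higher side. The deviations of libraries with the same number correlated at 0.02, -0.04 and 0.01, and not every library correlated best with its own number. These values show no pairing by number, but with 3 libraries per group they cannot exclude one. With the replicate block 8308 genes, 3378 past 2-fold, and 8 lists passed, the HIF targets (adjusted p = 0.057) and ribosome biogenesis (adjusted p = 0.087) not among them, and the PHF8 log2 fold change was -1.82. With as many other genes changed as were called, simulated changes of 1.5-fold were called in 91.0% of 67 genes with a mean of at least 50 reads; smaller changes and less abundant genes were not simulated, so a gene outside the calls is not shown to be unchanged.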

Other observations

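Of the tests in this part, those of pseudogene reads, of other nearly silent genes, of mixed control cells and of the ribosomal and respiratory lists were chosen after the result was seen, as was the length and GC offset. The genes named in the next paragraph were also chosen after their values were seen. The tests of neighbouring genes, of gene counts, of chromosome windows and of other splits were set before.

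A set of genes was nearly silent in knockout libraries 1 and 2 and partly expressed in knockout library 3. Of the genes with a mean of at least 100 reads in control cells, 15 besides GLUL had at most 2% of the control level in both libraries, and 12 of them held over 10% in library 3. GSTP1, a glutathione transferase, had 0.0% in libraries 1 and 2 and 42.4% in library 3, from a control mean of 667 reads. MYL9, a myosin light chain gene with 961 reads in control cells, had 0.32%, 0.31% and 35.2%, and DNAJC15, a mitochondrial co-chaperone gene, had 0.23%, 0.44% and 25.4%. MAGEA3, whose reads may be shared with other MAGEA genes, had 1.16%, 0.84% and 51.8%. The same rule applied to knockout library 1 or 2 found 0 genes. Over the tested genes, though, knockout library 2 stood apart. Chi-square per degree of freedom was 11.3 between knockout libraries 1 and 3, against 75.7 between 1 and 2 and 58.9 between 2 and 3. In the other direction, 21 genes high in knockout libraries 1 and 2 and at most 10% of that level in control cells lay at a median of 91.9% of it in library 3.

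Control cells or control RNA mixed into knockout library 3 would leave one share of the control level in all 15 genes. The tables argue against this, because the shares ran from 2.20% to 77.5%, with a 90th to 10th percentile ratio of 8.25. RAB31, at 3.64%, leaves little room for a larger admixture. A different makeup of edited cells, or a different guide RNA, in library 3 stays open and was not tested. The labels do not say whether the cells were a pool or clones, or what the library numbers mark. Any effect of PHF8 loss itself on these genes is also untested.

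The absence of GLUL reads in all 3 knockout libraries was shared by no other gene with a mean of at least 100 reads in control cells. A loss of the region around GLUL that reaches its neighbours is argued against, since the 5 tested genes within 1 Mb had a median log2 fold change of 0.94 (SE 0.80, from -0.63 for DHX9 to 3.12 for NPL); all 5 lie on one side of it, so a smaller deletion, or one towards the other side, stays open. Whether reads moved to GLUL pseudogenes cannot be told apart, because the 6 GLULP symbols had 0 reads in all libraries, those of control cells included (a knockout minus control sum of 0), and reads shared between copies may not be counted at all. Whether it is an extreme of the falls described above cannot be told apart, because only 15 such genes exist; 0 of the 15 had 0 reads in all 3 knockout libraries, and at their lowest share GLUL would have 8.76 reads in library 3. A deletion confined to GLUL, complete silencing in the founding cells of the knockout libraries, and a step specific to this gene in the counting or in the making of the table may each give such zeros and were not tested; SHISA2, with at least 64.7-fold less, was the only other gene with at least 30 reads in each control and 0 in each knockout library.

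The number of called genes, 8593, was 59.7% of those tested. Length and GC bias between libraries was to be argued against if the count held with an offset for both, and 8429 genes passed. That count alone cannot decide, because 2334 of these genes passed only with the offset. Of the original calls, 5659 passed in the same direction after the smooth trends were removed, 2498 were lost and 436 turned direction. For the ribosomal protein and oxidative phosphorylation lists, both calls ended with the offset, as was set for such a bias (camera adjusted p = 0.80 and 0.52, medians from 0.33 to -0.04 and from 0.35 to 0.07). This cannot tell a bias from a change in the cells, because the offset removes any group difference that follows length or GC content. Copy-number differences between the cells stay open: windows of 5 Mb explained 13.9 percentage points more variance of the fold changes than permuted positions, which met the bound of 10 set before the result was seen, but 5.46 points with the offset, between that bound and the one of 2 below which they were to be excluded. That second reading was added after the result was seen, and GC content, which also varies along chromosomes, cannot be told apart from copy number here. By chromosome, the median log2 fold change with the offset was highest on chromosome 16, 0.32 (0.48 without it). It was lowest on chromosome 7, -0.24 (-0.26 without it). In wider windows, which were not part of the test, medians with the offset ran further. They ran from -0.76 on chromosome 4, 80000001 to 100000000 (-1.12 without it), to 0.63 on chromosome 18, 40000001 to 60000000 (-0.03 without it). PLAC8 lies in that window of chromosome 4, and how much of its fall is shared with the window was not tested. Several rises named above lie on chromosome 16, among them MVD, GPT2, NUPR1 and MT1X. How much of their rise is shared with the whole chromosome was not tested.

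Of the 10 ways to split the 6 libraries into groups of 3, 1 gave as many genes, the real one, with 8593 against a highest of 0 in the others. The same held past 2-fold, where 1 of the 10 splits gave as many (3362 against a highest of 0), and for the lists, where 1 of the 10 did (10 against 4 to 7 in the others). The splits are too few for a share under 0.05. Each other split also mixes control and knockout libraries on both sides, so any large difference between the real groups keeps its gene counts low, whatever the cause.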
